A study of Mus musculus with 8 samples.

How the data were processed

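The 8 libraries were made from mouse retina, 4 labelled sIVs and 4 labelled PBS, with poly(A) selection and a protocol that marks strand, and were sequenced as 150 bp paired-end reads, per the labels. The authors deposited raw counts per gene, whole numbers for 54532 Ensembl genes, in a table that also lists each gene's position, strand, length and biotype. They also deposited FPKM values, fragments per kilobase of gene length and library total. In each library the FPKM values equalled the counts divided by the listed gene length and the library total, times a constant between 0.943 and 1.03, so both tables hold the same measurement. The genome build is mm10, per the submitters' processing notes. The aligner, the counter and whether counting used strand are not given in the sources used here. Of 54495 genes shared with GENCODE M21, 53585 had the same start and end as in the deposited count table. No column of the tables belonged to a sample outside this comparison.

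Groups and replicate numbers came from the sample titles. The tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined; the closing paragraphs name the tests and settings chosen later. Genes were kept by filterByExpr with default settings, which left 17004 of 54532, while 22766 genes had no count in any library. Counts were scaled with TMM factors and tested with the quasi-likelihood F test of edgeR 4.0.16 (R 4.3.3), two-sided, with group as the only term and Benjamini-Hochberg adjustment at 0.05. Standard errors of log2 fold changes were derived from that test, as the absolute log2 fold change divided by the square root of F. The 95% confidence intervals used these standard errors, so both are approximate. CPM are counts scaled to the normalized library size. Alternatives used DESeq2 1.42.0, limma-voom with sample quality weights (limma 3.58.1), limma on log2(FPKM + 1) and log2(FPKM + 0.1), 1 surrogate variable from sva 3.50.0, other scaling factors and filters, a replicate block and each library left out in turn. A sex covariate was listed only for the case that libraries differed in Y-linked transcripts; it was not run, because all 8 libraries expressed them, although at differing levels. Depth was 13803958 to 16622259 counts per library.

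In total 41 gene lists with 698 members were fixed for retinal cell types, inflammation, stress, trophic factors, metabolism and tissues that a dissection can carry over. The 36 lists with at least 5 tested genes, leaving out the sex-linked list, were tested with camera on log2 CPM (prior count 2) with a preset correlation of 0.01, and again with an estimated correlation and with fry. Single values per library were compared with exact permutation tests over 70 arrangements (scipy 1.17.1). A list score is the mean over members of log2 CPM minus the mean of the gene over the 8 libraries.

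The named-gene rule took up to 12 genes in each direction among those past the threshold that were protein coding, at a mean of at least 1 CPM and without overlap between the groups. It took up to 4 members of each list past the threshold. For lists that passed camera or fit the question of neuroprotection it took the 2 members of smallest p, and where fewer than 10 genes passed, also the 10 genes of smallest p. No gene passed, so only these last parts applied, and they named 36 genes, of which some are not reported here.

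The tests were checked on counts simulated from the means and dispersions of these libraries with 200 genes changed by known folds. Of 100 calls by edgeR, 8 were false, and of 163 calls by DESeq2, 42 were false. A list of 22 genes changed 2-fold, the microglia and macrophage list, had a camera adjusted p of 1.11e-12 with the preset and 0.0151 with an estimated correlation. The simulated genes varied independently, whereas the estimated correlation of that list was 0.78 in the real libraries. The check therefore does not show how either setting performs on lists of correlated genes.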

Results

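RNA sequencing measured gene expression in mouse retina, the light-sensing nervous tissue at the back of the eye. The 8 libraries fell into 2 groups of 4. The first carried the label sIVs, the abbreviation of the series for small intracellular vesicles, which are membrane vesicles taken from inside cells. The second was the control group and carried the label PBS. Replicates were numbered 1, 3, 4 and 5 in each group. The title of the series concerns the uptake of such vesicles, drug delivery and protection of retinal neurons, so the comparison asked which retinal transcripts differed between vesicle and control retinas. The labels gave no dose, route, time after treatment or injury model, and no group with extracellular vesicles was analysed here. The labels numbered the libraries of each group as biosamples 1 to 4 but did not say whether these came from separate animals. The p-values therefore measure only the spread between these samples, which may include technical variation.

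The counts summed to 13803958, 16622259, 14752537 and 16216198 in PBS replicates 1, 3, 4 and 5, and to 14562047, 13915203, 16009589 and 14068670 in sIVs replicates 1, 3, 4 and 5. Mitochondrially encoded genes took 2.53% ± 0.184 (SD, n = 4) of the counts in the PBS group and 2.70% ± 0.379 (SD, n = 4) in the sIVs group (two-sided exact permutation p = 0.514). The 10 highest genes took 6.48% ± 1.01 (SD, n = 4) and 6.95% ± 0.881 (SD, n = 4) (exact permutation p = 0.514), and total counts differed by less than their spread (exact permutation p = 0.371). The 6 single values compared per library had adjusted p of at least 0.617, and 4 against 4 libraries cannot give an exact p below 0.0286. Between-library variation set the precision of the gene comparison: the common biological coefficient of variation was 0.254. No pair of libraries within a group was as close as counting noise allows, the lowest chi-square per degree of freedom being 6.65.

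Between sIVs and PBS retinas, no single gene passed the test. Of 17004 genes tested, 0 had an adjusted p under 0.05 in edgeR's quasi-likelihood test, and the lowest adjusted p was 0.81. At an unadjusted p under 0.05 there were 255 genes, 177 with a higher and 78 with a lower level in sIVs retinas. Uniform p-values would give 850, but over the 35 splits of these libraries into 4 and 4 the median was 273. The 255 genes are therefore not unusually few for these libraries. DESeq2 called 0 genes (494 unadjusted) and limma-voom with sample quality weights called 0 (455 unadjusted). The groups did not overlap for 341 genes, or 2.0% of those tested, against a chance share of 2.9%. In counts simulated from these libraries, the same edgeR test recovered 2% of genes changed 1.5-fold, 26% of those changed 2-fold, 72% of those changed 3-fold and 84% of those changed 4-fold. Differences of 2-fold or less in single genes were thus mostly not detectable. The simulated genes varied independently, without the shared variation between the real libraries, so recovery in the real data may be lower.

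The 10 genes of smallest p, none of which passed, included H2-Q7, a class I histocompatibility gene on chromosome 17 (35439155 to 35443773, mm10). It stood at 0.27 ± 0.178 CPM (counts scaled to library size; SD, n = 4) in PBS and 2.00 ± 1.29 CPM (SD, n = 4) in sIVs retinas, a log2 difference of 2.84 ± 0.60 (SE; edgeR adjusted p = 0.81), with each sIVs library above each PBS library. H2-Q7 belongs to a family of closely similar genes among which reads can be shared, so its level is uncertain. AC149090.1, a protein-coding gene on the unplaced scaffold JH584304.1 (52190 to 59690), stood at 256 ± 60.6 CPM in PBS and 120 ± 27.6 CPM in sIVs retinas (SD, n = 4 each; log2 difference -1.09 ± 0.23 SE; edgeR adjusted p = 0.81). Tcea3, a transcription elongation factor gene on chromosome 4 (136247729 to 136274898), stood at 2.01 ± 0.227 and 3.62 ± 0.638 CPM (SD, n = 4 each; log2 difference 0.85 ± 0.22 SE; edgeR adjusted p = 0.81).

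The other 7 genes were non-coding genes, pseudogenes or unclassified transcripts, each with an edgeR adjusted p of 0.81. Log2 differences were -2.27 for Gm11399, an antisense gene on chromosome 11 (3142048 to 3143363) that overlaps Sfi1, 2.06 for the pseudogene Gm2446, 1.45 for the pseudogene Gm15429 and 1.04 for the long non-coding Gm34655. They were -0.49 for the long non-coding D130017N08Rik, 1.35 for 2810405F15Rik, which overlaps G630016G05Rik, and 1.28 for the pseudogene Rpl30-ps10. Of these 7, D130017N08Rik had the highest level, at 14.5 ± 0.61 CPM in PBS and 10.3 ± 1.01 CPM in sIVs retinas (SD, n = 4 each). The sources used here do not say whether counting used strand, and pseudogenes share reads with their parent genes, so levels of the antisense gene, the overlapping genes and the pseudogenes are uncertain.

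**Figure D1:**
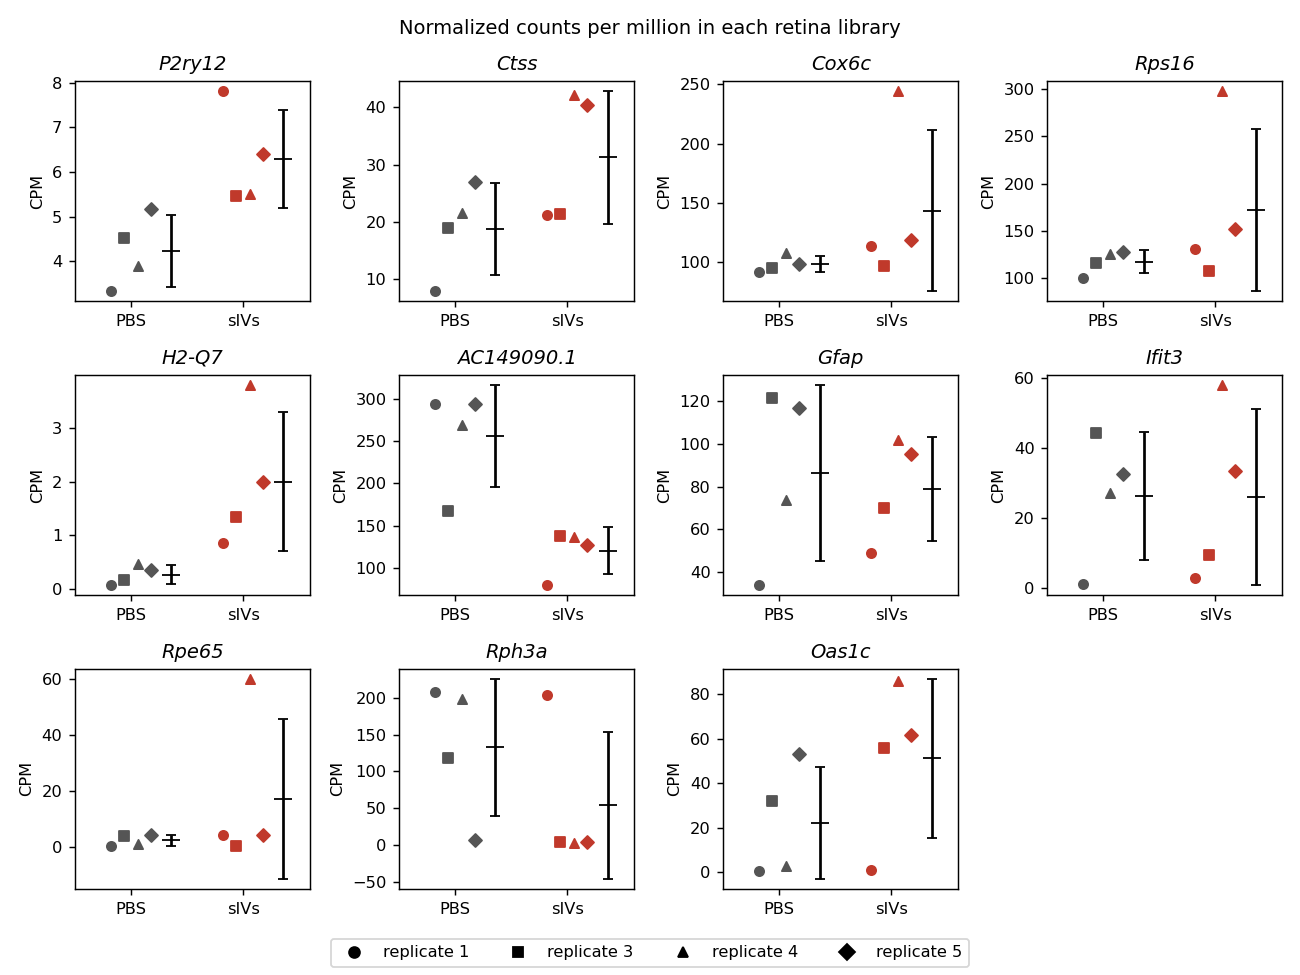
CPM of 11 genes in the 4 PBS (grey) and 4 sIVs (red) libraries, marker shape giving the replicate number, with the mean and SD (n = 4) of each group beside the points. P2ry12, H2-Q7 and AC149090.1 do not overlap between the groups although none passed the test over all genes, and Rpe65 reaches 60.2 CPM in sIVs replicate 4 alone; Gfap, Ifit3, Rpe65, Rph3a and Oas1c were chosen after their values were seen.

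Groups of genes were compared with camera, which asks whether the members of a list rank higher or lower than other genes. With the preset correlation of 0.01, 3 of 36 lists ranked higher in sIVs retinas, and no list passed downward. They were transcripts of microglia and macrophages, of nuclear-encoded oxidative phosphorylation and of the cytosolic ribosome, and none of these calls held with an estimated correlation. All 22 microglia and macrophage genes had a positive log2 fold change, with a median of 0.55 (camera adjusted p = 0.00211). Of 22 oxidative phosphorylation genes, 21 had a positive log2 fold change, with a median of 0.29 (camera adjusted p = 0.000383), as had 22 of 22 ribosomal protein genes, with a median of 0.34 (camera adjusted p = 0.000383). With an estimated correlation in place of the preset 0.01, each of the 3 calls was lost (adjusted p = 0.878 with an estimated correlation for each), and the self-contained test fry called 0 of the 36 lists, with a lowest adjusted p of 0.902.

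Members of these 3 lists differed in how far single libraries set their values. P2ry12, a purine receptor of resting microglia, stood at 4.23 ± 0.796 CPM in PBS and 6.29 ± 1.10 CPM in sIVs retinas without overlap (SD, n = 4 each; log2 difference 0.57 ± 0.21 SE; edgeR adjusted p = 0.81). Ctss, which encodes the lysosomal protease cathepsin S, stood at 18.8 ± 8.06 and 31.3 ± 11.6 CPM (SD, n = 4 each; log2 difference 0.73 ± 0.38 SE). Cox6c and Ndufa1, which encode subunits of respiratory complexes, had log2 differences of 0.54 ± 0.27 and 0.73 ± 0.35 (SE). Their levels in sIVs replicate 4 were 244 and 58.5 CPM, against no more than 118 and 25.4 CPM in the other 7 libraries. The ribosomal protein genes Rps16 and Rps27a had log2 differences of 0.55 ± 0.29 and 1.01 ± 0.51 (SE), with 298 and 368 CPM in sIVs replicate 4 and no more than 152 and 169 CPM in the others. Without that library the differences of Cox6c, Ndufa1, Rps16 and Rps27a were 0.16, 0.22, 0.14 and 0.35, while those of P2ry12 and Ctss were 0.63 and 0.55. No member of the 3 lists passed over all genes, and 0 passed when adjusted over the list alone; the lowest adjusted p over the list were 0.537, 0.286 and 0.248 for microglia, oxidative phosphorylation and ribosome.

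Single libraries decided these group calls. Without sIVs replicate 4, 0 of the 36 lists passed. The lowest camera adjusted p was 0.0548, for microglia (median 0.43). It was 0.37 for oxidative phosphorylation (median 0.05) and 0.858 for the ribosome (median 0.03). Without PBS replicate 1 the microglia median was 0.01 (adjusted p = 0.729), and without sIVs replicate 5 it was 0.28 (adjusted p = 0.125). The number of lists past the threshold was 7, 8, 4 and 10 without PBS replicates 1, 3, 4 and 5 in turn. It was 11, 6 and 4 without sIVs replicates 1, 3 and 5. With an estimated correlation, 0 lists passed in each of these settings. Markers of the retinal pigment epithelium, the pigmented layer next to the photoreceptors, were highest in the same sIVs replicate 4, where Rpe65, Rgr and Ttr, named after their values were seen, stood at 60.2, 153 and 150 CPM, against at most 4.13, 20.4 and 14.8 CPM in the other 7 libraries.

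**Figure D2:**
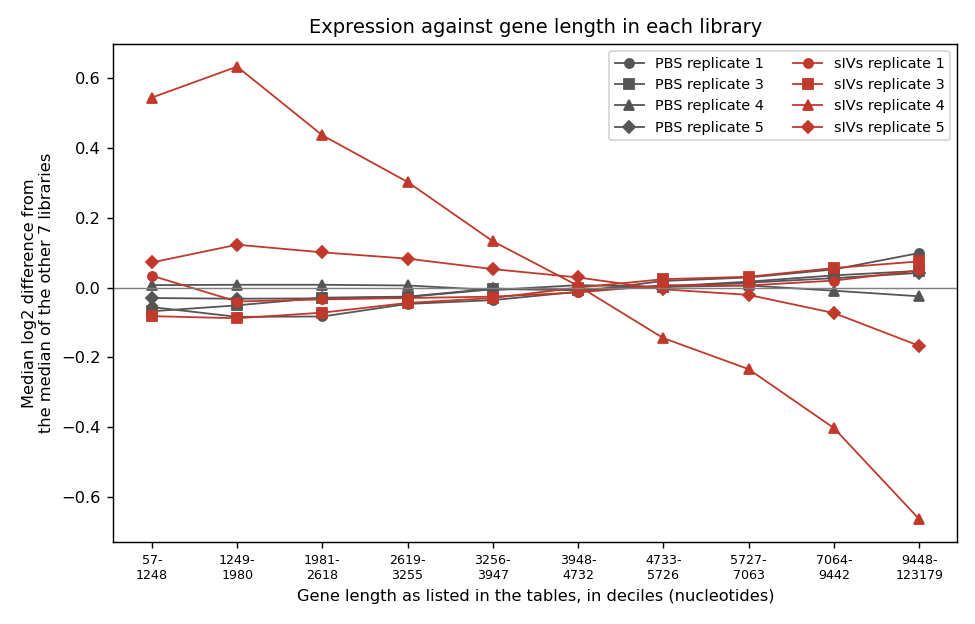
Median log2 difference of genes from the median of the other 7 libraries in 10 classes of gene length, for each PBS and sIVs library. In sIVs replicate 4 it is 0.545 in the shortest and -0.66 in the longest genes, and the plot was chosen after the values were seen.

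**Figure D3:**
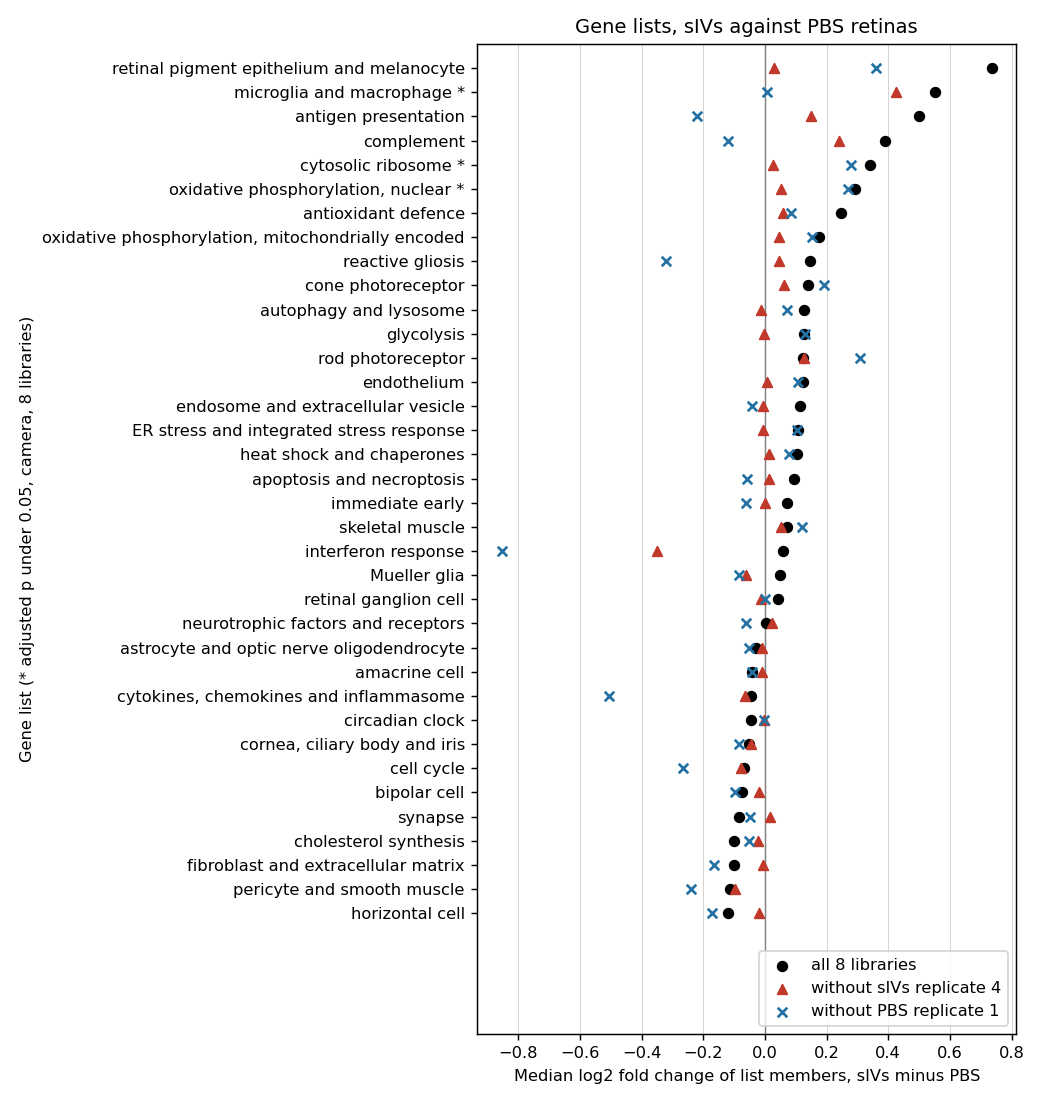
Median log2 fold change (sIVs minus PBS) of the members of each of 36 gene lists with all 8 libraries (circles), without sIVs replicate 4 (triangles) and without PBS replicate 1 (crosses), with asterisks at the 3 lists past adjusted p under 0.05 in camera with all 8. The ribosomal median goes from 0.34 to 0.03 without sIVs replicate 4, and the interferon median from 0.06 to -0.85 without PBS replicate 1.

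No gene of the photoreceptor and neuron lists, the ones closest to the question of neuroprotection, passed the test. Of 25 rod photoreceptor genes tested, 0 passed over all genes and 0 adjusted over the list alone; 18 had a positive log2 fold change, with a median of 0.12 (camera adjusted p = 0.237). Gngt1, a subunit of the rod G protein transducin, stood at 352 ± 52.8 CPM in PBS and 516 ± 220 CPM in sIVs retinas (SD, n = 4 each; log2 difference 0.55 ± 0.27 SE; edgeR adjusted p = 0.81). Guca1a, an activator of photoreceptor guanylate cyclase, had a log2 difference of 0.48 ± 0.28 (SE). Without sIVs replicate 4 the differences of Gngt1 and Guca1a were 0.23 and 0.14. Without PBS replicate 1 the rod list passed camera, with a median of 0.31 (camera adjusted p = 0.000206), as it did without sIVs replicate 5 (median 0.24; adjusted p = 0.0292) and without both PBS replicate 1 and sIVs replicate 4 (median 0.28; adjusted p = 2.19e-06), a setting chosen after seeing the data. With an estimated correlation these 3 calls were lost (adjusted p = 0.929, 0.866 and 0.914 with an estimated correlation).

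None of 15 cone, 16 retinal ganglion cell, 16 bipolar cell, 15 amacrine cell or 6 horizontal cell genes passed over all genes or adjusted over the list alone. Their lists had medians of 0.14, 0.04, -0.07, -0.04 and -0.12 (camera adjusted p = 0.223, 0.676, 0.358, 0.676 and 0.303). Pde6h, a subunit of the cone phosphodiesterase, had a log2 difference of 0.52 ± 0.28 (SE), and Rxrg, a retinoid receptor of cones, of 0.45 ± 0.24. Of the genes listed for ganglion cells, whose axons form the optic nerve, Tubb3 stood at 102 ± 7.56 CPM in PBS and 126 ± 31 CPM in sIVs retinas (SD, n = 4 each, log2 difference 0.31 ± 0.16 SE). Without sIVs replicate 4 the differences of Pde6h, Rxrg and Tubb3 were 0.11, 0.21 and 0.12. The ganglion cell transcription factor gene Pou4f1 stood at 49.6 ± 4.11 and 43.9 ± 1.48 CPM (SD, n = 4 each; log2 difference -0.17 ± 0.10 SE; edgeR adjusted p = 0.81). The synapse list had a median of -0.09 (camera adjusted p = 0.601).

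Glial, inflammatory and interferon transcripts varied more between libraries of a group than between the groups. Of 24 reactive gliosis genes, 0 passed over all genes and 0 adjusted over the list alone, with a median log2 fold change of 0.15 (camera adjusted p = 0.283). Mt1, a metallothionein gene, stood at 134 ± 76.3 CPM in PBS and 247 ± 234 CPM in sIVs retinas (SD, n = 4 each; log2 difference 0.88 ± 0.68 SE), and Cebpb, which encodes an acute-phase transcription factor, had a log2 difference of 0.63 ± 0.53. Among 16 genes of Müller glia, the radial support cells of the retina, the lipid carrier gene Apoe had a log2 difference of 0.72 ± 0.41 and the retinoid-binding protein gene Rlbp1 one of 0.25 ± 0.20 (SE; list median 0.05, camera adjusted p = 0.676). Without sIVs replicate 4, where Mt1 stood at 591 CPM, the differences of Mt1, Cebpb, Apoe and Rlbp1 were -0.03, 0.10, 0.25 and 0.01. Of 17 cytokine, chemokine and inflammasome genes, the chemokine genes Cxcl10 and Ccl2 had the smallest p, with log2 differences of -1.18 ± 0.92 and -1.05 ± 0.93 at no more than 4.45 and 3.01 CPM in any library (list median -0.04, camera adjusted p = 0.964).

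The 26 interferon response genes had a median log2 fold change of 0.06 (camera adjusted p = 0.964), the 16 antigen presentation genes one of 0.50 (adjusted p = 0.197) and the 14 complement genes one of 0.39 (adjusted p = 0.197). H2-Q7 was the only member of any of the 41 lists to pass when adjusted over the list alone (adjusted p = 0.0164, antigen presentation). Of the interferon genes, 10 had a positive and 16 a negative log2 fold change in edgeR, although the median of the differences in mean log2 CPM was above 0. PBS replicate 1 was lowest of the 8 libraries in all 3 lists. Without it the gliosis and interferon lists passed in the opposite direction, with medians of -0.32 (camera adjusted p = 0.0159) and -0.85 (adjusted p = 1.57e-06), and the cytokine list passed with a median of -0.51 (adjusted p = 0.00129). Gliosis genes passed upward without PBS replicate 3 (median 0.47), PBS replicate 5 (0.36) or sIVs replicate 1 (0.53), as did antigen presentation (0.73, 0.76 and 0.93) and complement genes (0.50, 0.77 and 0.57) without the same 3 libraries in turn. Leaving out each library in turn, 0 lists passed with an estimated correlation (lowest adjusted p = 0.77).

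**Figure D4:**
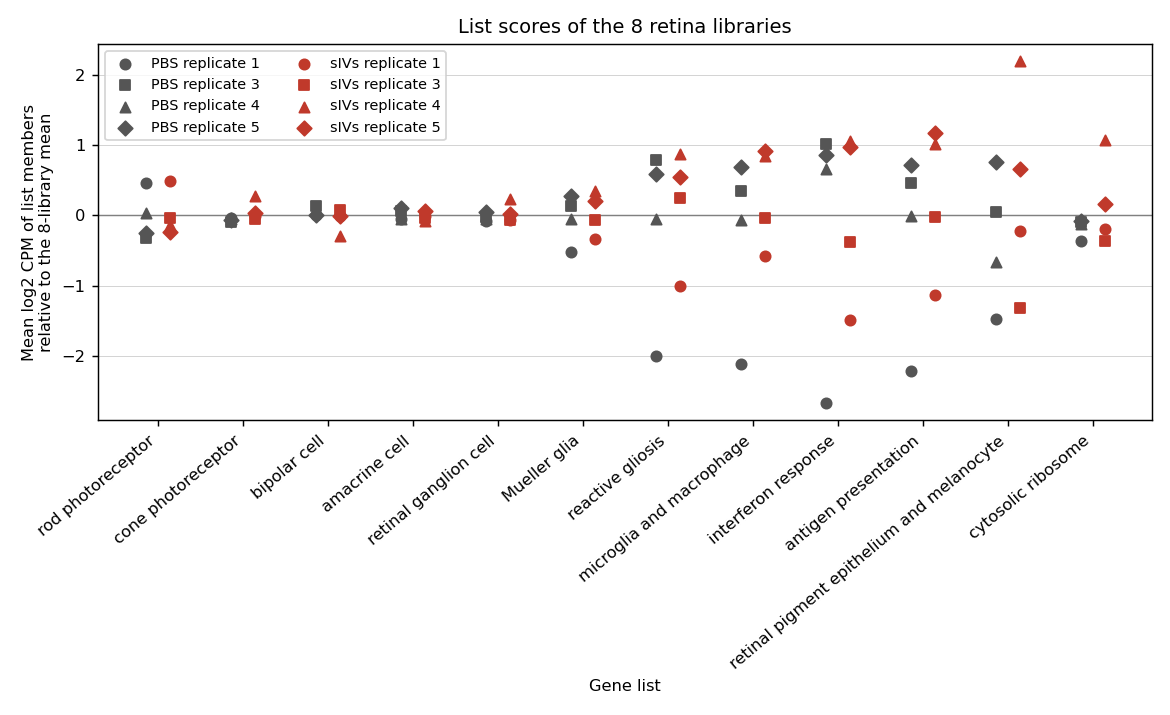
Mean log2 CPM of the members of 12 gene lists relative to the mean of the 8 libraries, for each PBS (grey) and sIVs (red) library, marker shape giving the replicate number. The gliosis score spans 2.87 log2 from PBS replicate 1 to sIVs replicate 4, while the amacrine cell score stays between -0.08 and 0.11.

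Cell death, stress and trophic genes did not pass either. Of 20 apoptosis and necroptosis genes, 0 passed over all genes and 0 adjusted over the list alone (median 0.10, camera adjusted p = 0.514). Bcl2l1, which encodes the survival protein Bcl-xL, had a log2 difference of 0.23 ± 0.16 (SE; edgeR adjusted p = 0.81). In the endoplasmic reticulum stress list (20 genes, median 0.11, camera adjusted p = 0.197), Ddit3 and Xbp1, both transcription factor genes of that response, had log2 differences of 0.36 ± 0.22 and 0.22 ± 0.15 (SE). In the antioxidant list (20 genes, median 0.25, camera adjusted p = 0.131), Gpx4, which reduces lipid peroxides, stood at 364 ± 21.6 and 523 ± 271 CPM (SD, n = 4 each), with 922 CPM in sIVs replicate 4, and the regulator gene Nfe2l2 had a log2 difference of 0.20 ± 0.12. The antioxidant list passed camera without PBS replicate 3 (median 0.24), PBS replicate 5 (0.29), sIVs replicate 1 (0.36) or sIVs replicate 3 (0.34), and the endoplasmic reticulum stress list without sIVs replicate 1 (0.21). With an estimated correlation these calls were lost (adjusted p = 0.839, 0.77, 0.77 and 0.933 for antioxidant genes and 0.77 for endoplasmic reticulum stress). Of 19 neurotrophic genes, 0 passed, and the list median of 0.002, mean of -0.02 and downward camera direction (adjusted p = 0.945) differed in sign. Serpinf1, which encodes pigment epithelium-derived factor, and Fgf1, a fibroblast growth factor gene, had log2 differences of 0.41 ± 0.23 and -0.18 ± 0.11 (SE). Without sIVs replicate 4 the differences were 0.05 for Bcl2l1, 0.07 for Ddit3, 0.05 for Xbp1, 0.10 for Gpx4, 0.12 for Nfe2l2, 0.32 for Serpinf1 and -0.11 for Fgf1.

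The endosome and extracellular vesicle list, the machinery by which cells take up and release vesicles, had 23 genes tested, of which 0 passed over all genes and 0 adjusted over the list alone (median 0.11, camera adjusted p = 0.676). Medians were 0.13 for autophagy and lysosome (camera adjusted p = 0.197), 0.10 for heat shock (0.223), 0.17 for mitochondrially encoded oxidative phosphorylation (0.197), 0.13 for glycolysis (0.206), -0.10 for cholesterol synthesis (0.283), -0.04 for the circadian clock (0.676) and -0.07 for the cell cycle (0.676). The autophagy list passed without PBS replicate 5 (median 0.14) or sIVs replicate 1 (0.22), and without sIVs replicate 1 so did heat shock (0.16) and cholesterol synthesis (-0.16); with an estimated correlation each of these calls was lost (adjusted p = 0.77). Immediate early genes had a median of 0.07 and a mean of -0.03 (camera direction down, adjusted p = 0.945).

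Among lists of cell types that a dissected retina can carry, none passed camera on log2 CPM with all 8 libraries and the count filter. The retinal pigment epithelium and melanocyte list had a median of 0.74 over 12 genes (camera adjusted p = 0.207), with 0.03 without sIVs replicate 4, and it passed without PBS replicate 5 (1.02) or sIVs replicate 3 (1.21), and with all 8 libraries where genes were ranked by the edgeR statistic (adjusted p = 0.0364). With an estimated correlation its adjusted p was 0.77 without PBS replicate 5, 0.933 without sIVs replicate 3 and 0.878 with all 8 libraries. Medians were 0.12 for endothelium (adjusted p = 0.231), -0.11 for pericytes and smooth muscle (0.458), -0.10 for fibroblasts and matrix (0.514; -0.27 and past the threshold without sIVs replicate 5, but 0.866 there with an estimated correlation), -0.05 for cornea, ciliary body and iris (0.676) and 0.07 for skeletal muscle (0.676). The astrocyte and oligodendrocyte list had a median of -0.03 and a mean of 0.10 (camera direction up, adjusted p = 0.676). Crystallins, other lens genes, blood leukocytes and erythrocytes had 2, 2, 2 and 4 genes tested and were too few for camera; none of these genes passed over all genes or adjusted over the list alone. Where 5 erythrocyte genes passed the count filter, that list passed camera upward: without PBS replicate 1 (median 1.10, adjusted p = 0.0159), PBS replicate 3 (1.13, 0.0148), PBS replicate 4 (1.18, 0.0189), PBS replicate 5 (0.90, 0.0213) and sIVs replicate 3 (1.37, 0.0155), as it did with 7 genes and no filter (0.83, 0.0422), but not with the same 7 genes on log2(FPKM + 1) (0.63, 0.0796). With an estimated correlation its adjusted p was at least 0.77 in these 6 settings. The erythrocyte score, over 4 genes, was 0.73 log2 higher in sIVs than in PBS retinas (exact permutation p = 0.057, unadjusted and the lowest of all list scores). The same permutation test gave p = 0.514 for microglia, 0.286 for nuclear-encoded oxidative phosphorylation and 0.457 for the ribosome. Y-linked Ddx3y had between 921 and 1237 counts in each library and Xist at most 7, so all 8 libraries had the transcripts of male mice.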

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

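Apart from the test of nuclear-retained RNAs, the tests of explanations were chosen or revised after values they measure had been seen, and the search for libraries far from their group followed a fixed rule. A first length test over all genes gave a Spearman rho of -0.446 in sIVs replicate 4 (-0.233 to 0.226 in the other 7 libraries), as a loss of long transcripts predicts. The 661 genes far lower in that library were nevertheless shorter (median 2583 nt) than all genes tested (3947.5 nt), so the test was divided into protein-coding and non-coding genes afterwards. Tests of pigment epithelium carry-over as the whole cause (median deviation of rod genes in sIVs replicate 4: 0.15 log2), of length for Rph3a and of the interferon score gap were dropped or replaced after their results were seen.

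A library far from the other 3 of its group was looked for in 156 groups of 4 values (6 values per library, 36 list scores and 36 named genes), and 9 were found, where about 1 in 20 groups, or 8, would be by chance. The measure is the gap to the nearest library divided by the range of the group, set against the 95% critical value of Dixon's test. PBS replicate 1 was low in the scores of the interferon response (0.904), immediate early genes (0.839) and the cytosolic ribosome (0.831). In sIVs replicate 4 the score of glycolysis (0.924) and the levels of 2810405F15Rik (0.871, at 2.75 CPM), Tubb3 (0.861, at 172 CPM) and Cox6c (0.855, at 244 CPM) were high. The skeletal muscle score was low in sIVs replicate 5 (0.86), and Pde6h was high in PBS replicate 5 (0.872, at 103 CPM).

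For the count of 0 changed genes the splits of the 8 libraries into 4 and 4 decide nothing, since all 35 must give at least 0; the highest of the others gave 1. Chance could not be excluded for the other 2 counts. For genes at an unadjusted p under 0.05, 19 of 35 splits gave at least the real 255, and the highest of the others gave 2928. That split set PBS replicates 1 and 4 and sIVs replicates 1 and 3 against the rest, which points to a structure of the samples that is not the treatment. All 35 of 35 splits gave at least the real 3 gene lists, the highest of the others giving 22.

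The library that stood farthest apart was sIVs replicate 4, with 661 genes at least 4-fold below the median of the other 7 libraries. Over protein-coding genes, its deviations correlated with gene length at a Spearman rho of -0.622, against -0.387 to 0.322 in the other libraries, so a loss of long transcripts may account for that part. Nktr stood at 15.8 CPM and Rgs9 at 21.7 CPM there. Over all genes its deviations also correlated with the share of G and C bases (rho 0.22, against -0.155 to 0.106 in the other 7 libraries). That relation was not told apart from the one with length. The listed gene length did not account for the non-coding part, here 511 TEC (unclassified) and sense-intronic genes. They lay at a median of -1.54 log2 against protein-coding genes of the same listed length. The length of the RNA molecules behind their counts was not measured, so the test cannot exclude a loss of long molecules there. A lower share of nuclear RNA also stays open for that part. The 11 nuclear-retained RNAs tested had a median of -0.23, with 6 of 11 below 0. The next lowest library in both measures was sIVs replicate 5, with a rho of -0.387 over protein-coding genes and a median of -0.43 log2 for TEC and sense-intronic genes. A vesicle effect shared by the whole group is argued against by sIVs replicates 1 and 3, 2 libraries whose length correlation lay within or above the range of the PBS libraries. An effect in only some sIVs libraries is not excluded by these values. Removing the length trend left 3 lists past camera's threshold with the preset correlation, and an estimated correlation was not run there. Medians went from 0.34 to 0.15 for the ribosome, from 0.29 to 0.16 for oxidative phosphorylation and from 0.55 to 0.51 for microglia. Leaving out sIVs replicate 4 ended the 3 calls at medians of 0.03, 0.05 and 0.425, although microglia only just missed the threshold (camera adjusted p = 0.0548).

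Reactive gliosis transcripts differed between libraries of the same group. Within PBS the gliosis score ranged over 2.79 log2, more than the difference of 0.33 between the group means, which argues against the vesicles as the whole source. A lower share of rods as the whole cause would raise the markers of other cell types alike, but the gliosis range exceeded the highest range of the bipolar, amacrine and ganglion cell scores by 2.44 log2. Loss of long transcripts is argued against too, because the range was still 2.79 log2 without sIVs replicates 4 and 5. Differences between retinas in injury, handling or time stay open, as the labels give none of these.

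Rph3a, which encodes the synaptic protein rabphilin 3A (chromosome 5, 120940499 to 121010092), stood at 209, 118, 198 and 7.16 CPM in PBS replicates 1, 3, 4 and 5 and at 204, 4.62, 2.75 and 3.99 CPM in sIVs replicates 1, 3, 4 and 5. Its neighbour Oas1c (chromosome 5, 120800194 to 120812514) went the other way, with 0.605, 32, 2.75 and 53 CPM and 1.22, 55.8, 86 and 61.7 CPM. Split at 10 CPM of Rph3a, 2 libraries, PBS replicate 5 and sIVs replicate 1, lay on the side of the other group. That argues against the vesicles as the whole cause. The remaining libraries lay on the side of their own group, so a partial effect of the vesicles is not excluded. Of 26 interferon genes, 25 were lower in sIVs replicate 3, with low Rph3a, than in PBS replicate 4, with high Rph3a. That argues against the interferon state as the whole cause. A candidate explanation is a genetic difference between the mice at this locus: 1 of 34 tested genes within 1 Mb, Oas1c, stepped with Rph3a (absolute r of at least 0.85 and a range over 4 log2), as did 2 in all of the genes tested, the other being Saa3 on chromosome 7. Expression alone cannot tell this apart from a shared regulation of the 2 genes, since no genotype was analysed here.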

How the results depend on the processing

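The settings that left out sIVs replicate 4 with PBS replicate 1, and that removed the length trend, were chosen after seeing the data. The count of changed genes was 0 in each setting except limma on log2(FPKM + 1), which called 1 gene, Gm49011, with 1 count in each sIVs library and 0 in each PBS library (adjusted p = 0.0114), so its call rests on counts at the floor; with a pseudocount of 0.1 the lowest adjusted p was 0.0666. Without each library in turn the count stayed at 0, with 136 to 958 genes at an unadjusted p under 0.05. Over all settings the median log2 fold change of all genes lay between -0.017 and 0.012.

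The 3 gene lists became 0 with an estimated correlation and 0 with fry, which do not use the preset, 4 where genes were ranked by the edgeR statistic (adding the pigment epithelium list, adjusted p = 0.0364), 4 without a count filter (adding erythrocytes), and ranged from 0 to 11 without each library in turn. They became 6 without both sIVs replicate 4 and PBS replicate 1, 5 of them in the downward direction; with an estimated correlation 0 passed there (lowest adjusted p = 0.914). In that setting the sign of the median turned for 22 of 35 lists, among them gliosis (median -0.43), microglia (-0.16, adjusted p = 0.516), interferon (-1.12), antigen presentation (-0.55), complement (-0.25), pigment epithelium (-0.32), Müller glia (-0.15) and ribosome (-0.031, adjusted p = 0.585). Without each library in turn, the median ran from -0.32 (PBS replicate 1) to 0.525 (sIVs replicate 1) for gliosis and from -0.85 (PBS replicate 1) to 0.601 (sIVs replicate 1) for interferon. The cause was not tested. With the length trend removed, the same 3 lists as in the main fit passed with the preset correlation (lowest camera adjusted p = 0.00483). An estimated correlation was not run in that setting, and in the main fit it gave these lists an adjusted p of 0.878. In at least 1 setting the sign of the fold change differed for 3 of 36 named genes and the direction given by the list test for 29 of 36 lists.

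The replicate block gave 0 genes (588 at an unadjusted p under 0.05) and 6 lists, of which 0 passed with an estimated correlation (lowest adjusted p = 0.848). The labels do not say what the shared numbers mark. Same-numbered libraries correlated at 0.596, 0.025, 0.227 and 0.514 in their deviations, not each over 0.1, so the numbers were not taken as pairs; 6 of 8 libraries correlated best with their own number, so a shared litter or day stays open. A sex covariate was not run, because all 8 libraries expressed Y-linked transcripts. Depth limits genes near 1 CPM, and 2-fold differences were recovered in 26% of simulated genes.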

Other observations

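The genes in this part and the test of the scores were chosen after their values were seen. Over the 8 libraries, scores of gliosis, microglia, antigen presentation and interferon genes went together and against that of rod genes; the relation was not tested within a group. PBS replicate 1 had the lowest level of the intermediate filament gene Gfap, of the endothelin gene Edn2, which photoreceptors and glia make under stress, and of Lcn2, which encodes the acute-phase protein lipocalin 2: 33.8, 3.10 and 2.12 CPM. The highest levels were 121 CPM of Gfap in PBS replicate 3 and 73.3 CPM of Edn2 and 210 CPM of Lcn2 in sIVs replicate 4. Ifit3, an interferon-induced gene, ran from 1.06 CPM in PBS replicate 1 to 58 CPM in sIVs replicate 4, and sIVs replicate 1 had the next lowest level, 2.87 CPM.

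The hypothesis that rod transcripts are lower where gliosis transcripts are higher was tested over the 8 libraries, as 1 of 9 relations of list scores with the gliosis score. Pearson's r was -0.931 (exact permutation p = 0.00228, adjusted p = 0.00513) and Spearman's rho was -0.833 (exact permutation p = 0.0154, adjusted p = 0.0277). The permutations treat the 8 libraries as exchangeable. Same-numbered libraries may share a litter or day, in which case the p-values of all 9 relations may be too small. Replicates 1 of both groups had the lowest gliosis scores and the highest rod scores. Without PBS replicate 1 and sIVs replicate 1, the 2 farthest from the median gliosis score, r was -0.798, and without sIVs replicates 4 and 5 it was -0.939. The gliosis score also went with those of Müller glia (r = 0.957, rho = 0.905), microglia (0.957, 0.833), antigen presentation (0.968, 0.81) and the interferon response (0.958, 0.952; 1 gene shared with the gliosis list), with adjusted exact permutation p of at most 0.00549 for r and 0.0327 for rho. Without the 2 farthest libraries these r were 0.854, 0.76, 0.736 and 0.576. Scores of bipolar (r = -0.148), amacrine (0.361) and cone cells (0.265) had adjusted exact permutation p of at least 0.507, and that of ganglion cells had r = 0.605 (adjusted exact permutation p = 0.183) and rho = 0.905 (adjusted p = 0.0137). Without sIVs replicates 4 and 5, r was 0.637 for bipolar, 0.612 for amacrine and -0.731 for cone cells, the bipolar and amacrine values in the direction that a lower share of rods gives. Rods hold much of the RNA of a retina, so their share may contribute to the relation; the bipolar and amacrine scores ranged over 0.144 and 0.161 log2 in those 6 libraries, against 2.789 for gliosis.

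Fbln1, Optc and Mfap4, matrix genes, separated replicates 5 of both groups from the other libraries. They stood at 109, 31.7 and 19.3 CPM in PBS replicate 5 and at 99.8, 24.6 and 20.8 CPM in sIVs replicate 5, and at no more than 13.4, 3.49 and 2.08 CPM in the other 6 libraries. Among the 6 tested genes on chromosome 11 between 3000000 and 3300000, 3 had an unadjusted p under 0.05: Gm11399, Pisd-ps1 (log2 difference -0.72) and Sfi1 (-0.43), each with no overlap between the groups and none past the test over all genes. Hbb-bs, a haemoglobin gene, stood at 2.24 ± 0.892 CPM in PBS and 5.95 ± 4.14 CPM in sIVs retinas (SD, n = 4 each; edgeR adjusted p = 0.81), with 11.2 CPM in sIVs replicate 4.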
